A study of Mus musculus with 20 samples.

How the data were processed

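RNA of mouse flank tissue was measured on 20 Affymetrix Mouse Genome 430 2.0 arrays, which were processed by a contract laboratory, per the labels. The values used here are the authors' deposited intensity values, 1 MAS5 signal per probe set and array on a linear scale, in 1 table of the whole series. Per the labels and the submitters' processing notes, the signals were made with the MAS 5.0 algorithm in GCOS 1.3, with background correction and a scaling factor of 1500. The strain, sex, dose of vector, injection protocol and the handling of RNA before hybridisation are not given in the sources used here. Each array was already scaled by the authors, so no further normalization was applied in the main setting.

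Groups were taken from the source name and title of each sample. Arrays were named by the letter of their title. Control had 5 arrays (A to E), day 5 had 4 (B to E), day 20 had 5 and day 60 had 5. The array with the title of day 5 A carried the source name and tissue field of the day 0 control, so it was left out of every comparison and counted as either group in alternatives only. No column of the table was left unused.

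The table held 45101 probe sets, of which 64 were AFFX controls. In the platform annotation 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none here. Symbols were updated through gene identifiers, and 34754 of the probe sets with 1 symbol matched the current gene table. Genes were named from probe sets with 1 symbol only. Each of 18193 genes was represented by its probe set with the highest mean over the 19 assigned arrays, and 13594 genes with a mean of at least 300 were tested.

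Tests used R 4.3.3 with limma 3.58.1 and statmod 1.5.0 on log2(signal + 100). All 19 assigned arrays entered a single fit of group means (lmFit, then eBayes with a trend), so that the 4 groups shared 1 estimate of the spread, and contrasts were tested on both sides. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05. Counts changed at least 2-fold were taken among these. The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

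A set of 33 gene lists with 616 genes (cell types, vessel classes, matrix, immune and tissue genes) was fixed from general knowledge. Of the members, 49 had no probe set of their own. The 31 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, against all other tested genes, and again with an estimated correlation. The other lists, of red cell and platelet genes, were too short to test. Within each list, member calls were also adjusted over the list alone. A list's array value was the mean log2(signal + 100) of its members.

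Named genes were chosen by rule. Against control these were Vegfa (with all its probe sets), Kdr, Flt1 and Pgf, then the 5 largest rises and 5 largest falls among passing genes whose arrays did not overlap, then the 2 most changed passing members of each of the 10 lists with the smallest p. Between days the numbers were 4, 4 and 1 member of each of 5 lists. Each time course class gave 3 genes, and Riken clones, Gm and LOC models were passed over. Members that went against their list, and members of counts of 5 or fewer, were named after their values were seen, as were Ccl2, Ccl7 and Arg1.

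Calls shared between days were set beside 100 simulations of unchanged groups against the same controls, beside the overlap of independent lists and beside splits of the control arrays into 2 and 3. The fit was tested on simulated data for 13594 genes with known changes. For day 5 against control it recovered 23.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 93.9% of those changed 4-fold. For day 20 the shares were 35.8%, 67.2% and 92.4%, and for day 60 26.9%, 74.6% and 97.0%. In a simulation of day 5, camera called 5 of 5 raised lists and none of the 19 others that shared no member with a raised list. The rest were not counted. Genes were simulated as independent, so this did not test camera on lists whose members vary together.

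Alternatives covered the pseudocount (1 and 500), the minimum signal (none and 1000), quantile normalization, centring on the 75th percentile, eBayes without a trend, array weights, a fit of only both compared groups, the choice of probe set, all probe sets, the letter of the title as a block, the placing of the unassigned array, fry in place of camera, an estimated correlation, split controls and the omission of each array in turn. Alternatives chosen after seeing the data were a pair of joint omissions and the Actb 3' to 5' ratio as a covariate. Probe set positions on transcripts need a genome sequence and were not analysed here.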

Results

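Flank tissue of mice was profiled on 20 arrays in a time course of Ad-VEGF-A164. This adenoviral vector makes infected cells produce the VEGF-A164 form of vascular endothelial growth factor A. The deposited values were MAS5 signals of 45101 probe sets per array. By the labels, 5 arrays were controls of day 0, 4 were of day 5 after the vector, 5 of day 20 and 5 of day 60. The remaining array had a title of day 5 but a source name of the day 0 control and entered no comparison. By its title the series concerns stromal signatures for sorting gastric cancers. Its time course asks which genes change while vessels form and afterwards. The number of arrays limits the precision. No label says that the arrays came from separate animals, so gene p-values measure only the spread between these samples, which may be technical. Controls were of day 0 only and no label names an empty vector, so VEGF-A, the vector, the injection and the time of harvest were not separable. Fold changes below are on the log2(signal + 100) scale, which understates the change of genes with low signal. List tests are limma's camera with Benjamini-Hochberg adjusted p-values. At the preset correlation these rest mainly on the spread between genes, not arrays. List averages are mean log2 changes, and parentheses after a list's counts give its higher and lower members adjusted over the list alone.

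The first principal component of the 19 assigned arrays held 40.3% of the variance and the second 12.9%. No pair of arrays held identical values. The median signal averaged 500.6 in control, 451.5 on day 5, 458.3 on day 20 and 480.5 on day 60, and 37.8%, 40.2%, 39.6% and 38.9% of probe sets lay under 300. The ratio of 3' to 5' signal of Actb, a sign of RNA integrity that grows as RNA breaks down, was 7.10 ± 1.89 in control (SD, n = 5), 4.82 ± 1.96 on day 5 (n = 4), 4.48 ± 1.84 on day 20 (n = 5) and 8.82 ± 4.24 on day 60 (n = 5). The day 60 arrays A, B and D had ratios of 14.0, 10.4 and 10.9. The same ratio for Gapdh averaged 2.26, 1.86, 2.15 and 3.46.

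**Figure D1:**
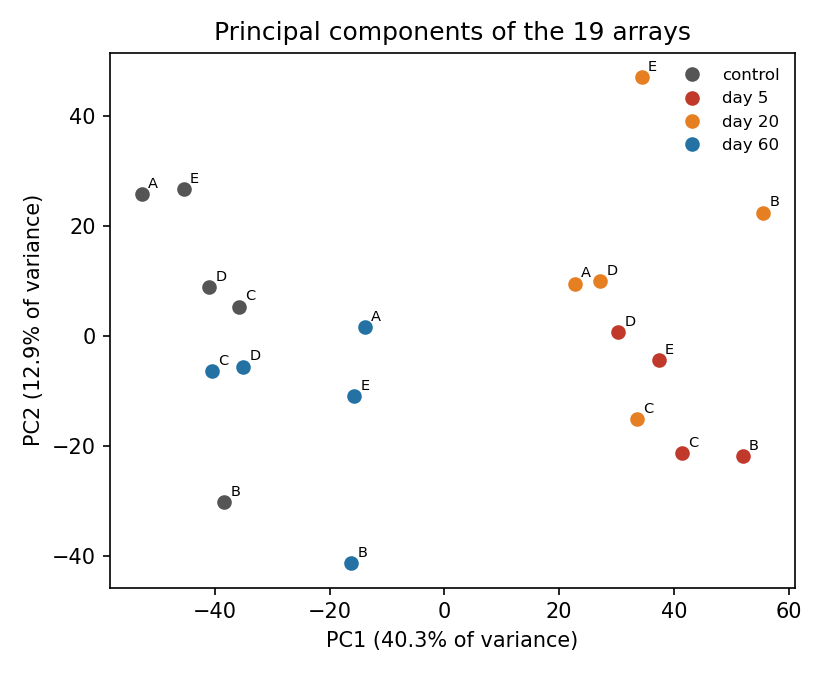
First and second principal components (40.3% and 12.9% of the variance) of log2(signal + 100) over 13594 genes, with 1 point per assigned array coloured by group. Axes are component scores without units.

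The vector's gene was examined first, because it checks the labels. Vegfa is read by 2 probe sets named for that gene alone. On the probe set with the higher mean the signal was 197 ± 156 in control (SD, n = 5), 6739 ± 2584 on day 5 (n = 4), 9256 ± 2549 on day 20 (n = 5) and 463 ± 354 on day 60 (n = 5). It rose 23.8-fold on day 5 (log2 change 4.57 ± 0.37, SE, limma adjusted p = 6.46e-08) and 33.6-fold on day 20 (log2 change 5.07 ± 0.35, adjusted p = 5.93e-09), with every array above every control array. On day 60 the log2 change was 0.88 ± 0.35 (adjusted p = 0.214). The other probe set went the opposite way, from 2022 ± 479 in control to 719.9 ± 66.1 on day 5, 1029 ± 146 on day 20 and 1750.1 ± 499 on day 60. Its log2 change was -1.34 on day 5 (adjusted p = 5.94e-05), -0.89 on day 20 (adjusted p = 0.00197) and -0.22 on day 60 (adjusted p = 0.645). Where each probe set lies on the Vegfa transcript was not analysed here, so the direction of Vegfa holds for the named probe set only. Both probe sets were called in opposite directions, and with Vegfa included 88 of the 5763 genes with several tested probe sets had calls both ways on day 5.

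**Figure D2:**
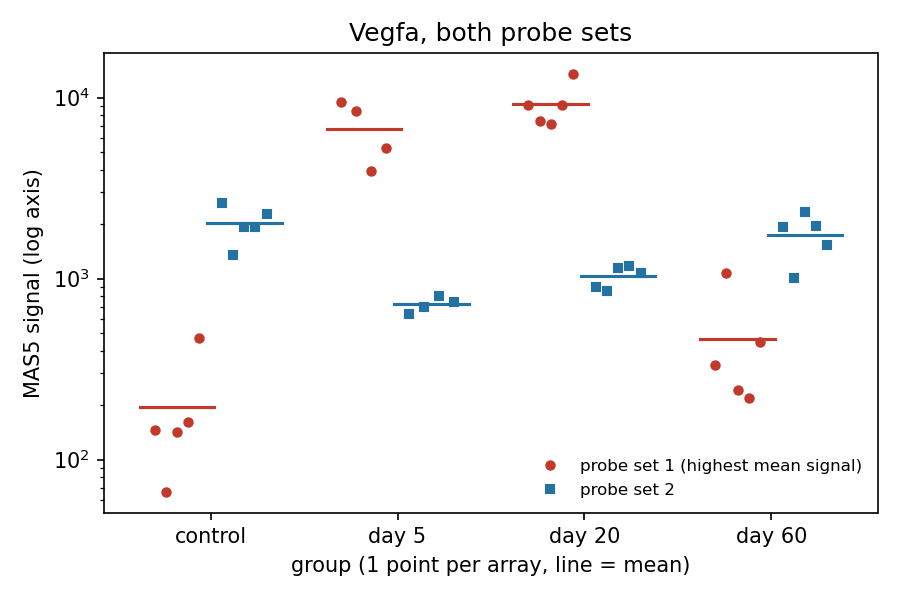
MAS5 signal of both Vegfa probe sets on a log axis, with 1 point per array and a line at each group mean. One probe set rises from a mean of 197 in control to 9256 on day 20 and the other drops from 2022 to 1029.

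Day 5 against control asked which genes changed while new vessels were growing. Kcne3, a potassium channel subunit of sprouting tip cells, rose 41.4-fold, from 103 ± 38.2 to 8247 ± 1246 (SD, n = 5 and n = 4; log2 change 5.37 ± 0.26, SE, limma adjusted p = 1.03e-10). Esm1, the endothelial proteoglycan endocan, rose 29.8-fold, from 904 ± 304 to 29185 ± 5584. Tmem255a rose 21.4-fold and Notch4, an endothelial Notch receptor, 20.7-fold. The VEGF receptor genes rose less: Flt1 4.85-fold (log2 change 2.28 ± 0.26, adjusted p = 2.72e-06) and Kdr 3.05-fold (1.61 ± 0.25, adjusted p = 6.3e-05). Pgf, a ligand of Flt1, rose 2.98-fold (1.57 ± 0.39, adjusted p = 0.00403). In each of these genes all 4 day 5 arrays lay above all 5 control arrays.

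Foxa1, a transcription factor of luminal epithelia, fell 42.1-fold from 7415 ± 2189 to 90.9 ± 106 (SD, n = 5 and n = 4; log2 change -5.40 ± 0.58, SE, limma adjusted p = 1.14e-06). Pgr, the progesterone receptor, fell 21.8-fold and Clca3a2, a chloride channel accessory protein, 34.3-fold. Thrsp, a regulator of fatty acid synthesis, fell 32.6-fold from 41194 ± 32883 to 977 ± 604, and Ces1d, an adipocyte lipase, fell 32.0-fold. H2-Q10, a secreted class I molecule, had a log2 change of -4.12 ± 0.58 (adjusted p = 2.62e-05). All 4 day 5 arrays lay below all 5 control arrays in each of them, which the choice of all but H2-Q10 required.

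Endothelial lists rose on day 5. Of 30 pan-endothelial markers 28 rose, 1 fell and 1 did not pass (28 and 1 over the list alone). They averaged 1.63 (adjusted p = 5.64e-21). Icam2, an adhesion molecule, rose 9.10-fold and the sialomucin Emcn 8.28-fold, while Vwf, the clotting factor stored in endothelium, was the member that fell (log2 change -1.15 ± 0.39). Of 22 sprouting tip cell genes 18 rose and 4 did not pass (20 and 0 over the list alone). They averaged 1.91 (adjusted p = 1.24e-16). Of the 14 VEGF and angiopoietin ligands and receptors 9 rose, 2 fell and 3 did not pass (10 and 2 over the list alone). They averaged 1.28 (adjusted p = 2.15e-05). Tie1, an endothelial receptor, rose 6.93-fold, and the members that fell were Vegfb (-1.29 ± 0.45) and the vessel-stabilising ligand Angpt1 (-0.99 ± 0.14). Of 19 Notch pathway and arterial genes 11 rose and 8 did not pass (11 and 0 over the list alone). They averaged 0.78 (adjusted p = 6.74e-05, and adjusted p = 0.173 with an estimated correlation). Of 9 venous genes 4 rose, 2 fell and 3 did not pass (6 and 2 over the list alone). They averaged 0.60 (adjusted p = 0.0477, and adjusted p = 0.214 with an estimated correlation), and Vwf and Ackr1, a chemokine-binding protein of venules, fell. The venous call ended without control A, control C, day 5 D, day 5 E, day 20 E or day 60 E (adjusted p = 0.0521, 0.0712, 0.0605, 0.0913, 0.0526 and 0.0562). Of 10 lymphatic genes 4 rose, 1 fell and 5 did not pass (4 and 1 over the list alone), and the list was not shifted (adjusted p = 0.0877).

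Proliferation and matrix genes rose together with the endothelial lists. Of 43 cell cycle genes 40 rose and 3 did not pass (40 and 1 over the list alone). They averaged 1.54 (adjusted p = 1.1e-25). The mitotic checkpoint kinase gene Bub1 rose 6.97-fold and the cyclin gene Ccnb2 6.23-fold. Of 27 fibrillar matrix genes 21 rose, 3 fell and 3 did not pass (21 and 3 over the list alone). They averaged 1.35 (adjusted p = 2.27e-09, and adjusted p = 0.204 with an estimated correlation). Timp1, a metalloproteinase inhibitor, rose 17.1-fold and the matrix glycoprotein gene Tnc 11.1-fold, while Lum, Dcn and Eln, which encode lumican, decorin and elastin of resting connective tissue, fell (log2 changes -1.47, -1.42 and -0.57). Of 14 basement membrane genes 9 rose, 1 fell and 4 did not pass (9 and 2 over the list alone). They averaged 1.17 (adjusted p = 2.15e-05, and adjusted p = 0.123 with an estimated correlation), with the laminin-binding Nid2 (12.1-fold) and the collagen chain Col4a2 (7.24-fold). Of 21 matrix proteases and inhibitors 10 rose, 2 fell and 9 did not pass (10 and 2 over the list alone). They averaged 0.87 (adjusted p = 0.00235, and adjusted p = 0.296 with an estimated correlation), and the inhibitor genes Timp4 (-1.50) and Timp2 (-1.39) fell. Of 20 pericyte and smooth muscle genes 12 rose, 3 fell and 5 did not pass (13 and 3 over the list alone). They averaged 0.70 (adjusted p = 0.000195, and adjusted p = 0.173 with an estimated correlation). Genes of contractile muscle were those that fell: Synpo2 (-1.71), Lmod1 (-1.45) and Pln (-1.02).

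Of 18 macrophage markers 15 rose, 1 fell and 2 did not pass (16 and 1 over the list alone). They averaged 1.88 (adjusted p = 8.79e-10, and adjusted p = 0.2 with an estimated correlation). The scavenger receptor gene Msr1 rose 8.57-fold and the Fc receptor gene Fcgr3 7.82-fold, and Cd14 fell (-0.82). Of 27 interferon-stimulated genes 19 rose and 8 did not pass (22 and 0 over the list alone). They averaged 1.03 (adjusted p = 6.53e-09, and adjusted p = 0.2 with an estimated correlation). The guanylate-binding protein gene Gbp3 rose 3.52-fold and the antiviral gene Rsad2 3.45-fold. Of 16 antigen presentation genes 12 rose and 4 did not pass (12 and 0 over the list alone). They averaged 0.68 (adjusted p = 7.04e-05, and adjusted p = 0.204 with an estimated correlation). Of 20 inflammatory cytokines and chemokines 8 rose, 1 fell and 11 did not pass (8 and 2 over the list alone). They averaged 0.95 (adjusted p = 0.0045, and adjusted p = 0.4 with an estimated correlation). The monocyte chemokine genes Ccl2 (3.67 ± 0.31) and Ccl7 (3.06 ± 0.45) rose and Arg1 fell (-1.24).

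Several lists of resident tissue were lower on day 5. Of 21 adipocyte genes 18 fell and 3 did not pass (0 and 18 over the list alone). They averaged -1.96 (adjusted p = 1.23e-09, and adjusted p = 0.2 with an estimated correlation), and the gluconeogenic enzyme gene Pck1 fell 9.03-fold. Of 7 thermogenic fat genes 5 fell and 2 did not pass (0 and 7 over the list alone). They averaged -1.80 (adjusted p = 0.00917, and adjusted p = 0.262 with an estimated correlation). Of 28 skeletal muscle genes 13 fell and 15 did not pass (0 and 14 over the list alone). They averaged -1.40 (adjusted p = 7.11e-05, and adjusted p = 0.535 with an estimated correlation). Of 22 mitochondrial respiration genes 16 fell and 6 did not pass (0 and 21 over the list alone). They averaged -0.79 (adjusted p = 2.15e-05, and adjusted p = 0.427 with an estimated correlation). The cytochrome oxidase subunit gene Cox6a2, which is expressed in muscle, fell 4.60-fold and the complex III gene Uqcrfs1 2.24-fold. The Cox6a2 call ended without day 5 B (adjusted p = 0.118). Of 10 Schwann cell and myelin genes 5 fell and 5 did not pass (0 and 5 over the list alone). They averaged -0.77 (adjusted p = 0.007, and adjusted p = 0.2 with an estimated correlation).

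Other lists were not shifted on day 5. These were neutrophil markers (3 higher and 2 lower of 11, adjusted p = 0.266), mast cell markers (1 higher and 1 lower of 8, adjusted p = 0.689), T and NK cell markers (2 higher and 1 lower of 8, adjusted p = 0.438), B and plasma cell markers (0 higher and 1 lower of 6, adjusted p = 0.555) and complement genes (6 higher and 2 lower of 11, adjusted p = 0.163). The same held for hypoxia and glycolysis genes (4 higher and 8 lower of 21, adjusted p = 0.466), immediate VEGF response genes (3 higher and 2 lower of 16, adjusted p = 0.948) and muscle regeneration genes (2 higher and 2 lower of 9, adjusted p = 0.58). Epidermis genes (0 higher and 0 lower of 21, adjusted p = 0.0877), hair follicle genes (0 higher and 1 lower of 20, adjusted p = 0.342) and ribosomal protein genes (1 higher and 0 lower of 17, adjusted p = 0.128) were not shifted either. In all, 2285 genes rose and 2373 fell of 13594 tested, or 34.3% (2383 and 2196 when each array was centred on its 75th percentile, which turned the balance), of which 957 and 818 changed at least 2-fold (with pseudocount 500 510 lower). Among the 31 lists 14 were higher and 5 lower, each with all 4 day 5 arrays beyond all 5 control arrays in its mean. With an estimated correlation 4 calls held: pan-endothelial (adjusted p = 0.047), tip cell (0.0148), VEGF (0.0481) and cell cycle (0.0481). Counted as a control, the unassigned array left 1269 falling genes. Its values go against that place, with a Vegfa signal of 11111.1 beside at most 467 in the controls.

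Day 20 against control asked which changes were present after longer exposure to the growth factor. The largest rise was in Mmp13, a collagenase, which rose 67.3-fold from 102 ± 70.4 to 15518 ± 11769 (SD, n = 5 each; log2 change 6.07 ± 0.57, SE, limma adjusted p = 2.66e-07). Mgp, an inhibitor of calcification in vessel walls, rose 28.1-fold to 55004 ± 7100.1. Esm1 rose 30.9-fold and Kcne3 22.7-fold. Flt1 rose 4.08-fold (2.03 ± 0.25, adjusted p = 5.33e-06), Kdr 3.45-fold (1.79 ± 0.23, adjusted p = 1.14e-05) and Pgf 3.31-fold (1.73 ± 0.37, adjusted p = 0.00142). The largest falls were in Foxa1 (47.3-fold), Clca3a2 (40.2-fold), Thrsp (39.8-fold), the cytochrome P450 gene Cyp2e1 (32.1-fold) and Ces1d (31.1-fold). All 5 day 20 arrays lay apart from all 5 control arrays in each of these genes.

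Vessel lists rose on day 20. Of 30 pan-endothelial markers 27 rose and 3 did not pass (27 and 0 over the list alone). They averaged 1.54 (adjusted p = 1.03e-22), with Emcn (7.18-fold) and Icam2 (5.13-fold). Of 22 tip cell genes 20 rose and 2 did not pass (22 and 0 over the list alone). They averaged 1.84 (adjusted p = 2.58e-18). Of 14 VEGF and angiopoietin genes 11 rose and 3 did not pass (11 and 0 over the list alone). They averaged 1.45 (adjusted p = 1.3e-07), with Angpt2, a ligand that loosens vessels (4.71-fold). Of 20 pericyte and smooth muscle genes 16 rose, 1 fell and 3 did not pass (16 and 1 over the list alone). They averaged 1.39 (adjusted p = 2.29e-11). Mcam, an adhesion molecule of pericytes and endothelium, rose 7.18-fold and the pericyte marker Rgs5 5.82-fold, from 19587 ± 4744 to 112653 ± 15159. Of 14 basement membrane genes 10 rose, 1 fell and 3 did not pass (10 and 1 over the list alone). They averaged 1.35 (adjusted p = 2.5e-08), with Nid2 (11.1-fold) and Col4a2 (10.2-fold). Of 9 venous genes 6 rose and 3 did not pass (7 and 0 over the list alone). They averaged 1.08 (adjusted p = 0.000107). Of 19 Notch and arterial genes 13 rose and 6 did not pass (14 and 0 over the list alone). They averaged 0.91 (adjusted p = 4.06e-07, and adjusted p = 0.053 with an estimated correlation), with Notch4 (9.05-fold) and the arterial transcription factor gene Sox17 (4.07-fold). Of 10 lymphatic genes 5 rose and 5 did not pass (6 and 1 over the list alone). They averaged 1.03 (adjusted p = 0.00287, and adjusted p = 0.189 with an estimated correlation).

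Of 27 fibrillar matrix genes 23 rose, 1 fell and 3 did not pass (23 and 1 over the list alone) on day 20. They averaged 1.65 (adjusted p = 3.02e-16, and adjusted p = 0.0864 with an estimated correlation), with the collagen gene Col12a1 (12.2-fold) and Timp1 (9.50-fold). Of 21 matrix proteases and inhibitors 11 rose, 1 fell and 9 did not pass (12 and 2 over the list alone). They averaged 1.15 (adjusted p = 3.84e-05, and adjusted p = 0.173 with an estimated correlation), with the macrophage elastase gene Mmp12 (11.4-fold). Of 43 cell cycle genes 34 rose and 9 did not pass (38 and 0 over the list alone). They averaged 0.93 (adjusted p = 2.57e-15, and adjusted p = 0.0911 with an estimated correlation), with the kinetochore gene Nuf2 (5.60-fold) and Bub1 (4.20-fold). Of 18 macrophage markers 9 rose, 2 fell and 7 did not pass (10 and 2 over the list alone). They averaged 0.81 (adjusted p = 0.000282, and adjusted p = 0.409 with an estimated correlation), and Cd163, a haemoglobin scavenger receptor, and Cd14 fell (-1.60 and -0.91). Of 27 interferon-stimulated genes 9 rose and 18 did not pass (9 and 0 over the list alone). They averaged 0.52 (adjusted p = 0.00123, and adjusted p = 0.409 with an estimated correlation). Of 16 antigen presentation genes 6 rose and 10 did not pass (7 and 0 over the list alone). They averaged 0.64 (adjusted p = 0.00116, and adjusted p = 0.319 with an estimated correlation). Of 20 cytokines and chemokines 7 rose and 13 did not pass (8 and 0 over the list alone). They averaged 0.63 (adjusted p = 0.0109, and adjusted p = 0.409 with an estimated correlation).

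Of 21 adipocyte genes 18 fell and 3 did not pass (0 and 19 over the list alone) on day 20. They averaged -2.35 (adjusted p = 1.68e-12, and adjusted p = 0.101 with an estimated correlation), and Pck1 fell 28.8-fold. Of 7 thermogenic genes 4 fell and 3 did not pass (0 and 5 over the list alone). They averaged -1.58 (adjusted p = 0.00783, and adjusted p = 0.297 with an estimated correlation). Of 28 skeletal muscle genes 6 fell and 22 did not pass (0 and 5 over the list alone). They averaged -1.002 (adjusted p = 0.00116, and adjusted p = 0.542 with an estimated correlation). Of 22 mitochondrial respiration genes 8 fell and 14 did not pass (0 and 11 over the list alone). They averaged -0.56 (adjusted p = 0.000183, and adjusted p = 0.456 with an estimated correlation). Skin lists were lower. Of 21 epidermis genes 10 fell and 11 did not pass (0 and 13 over the list alone). They averaged -1.24 (adjusted p = 0.000132, and adjusted p = 0.409 with an estimated correlation). Of 20 hair follicle genes 11 fell and 9 did not pass (0 and 12 over the list alone). They averaged -1.12 (adjusted p = 0.000104, and adjusted p = 0.409 with an estimated correlation). In both skin lists day 20 A and C lay within the range of the controls, as did D for hair follicle genes, where B and E lay at 10.312 and 10.125 and the controls from 11.942 to 13.513. Of 10 Schwann cell and myelin genes 2 fell and 8 did not pass (0 and 4 over the list alone). They averaged -0.47 (adjusted p = 0.0384, and adjusted p = 0.319 with an estimated correlation). The Schwann call ended without control B, control D, day 20 D or day 20 E (adjusted p = 0.0514, 0.0784, 0.0678 and 0.0594).

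Neutrophil, mast cell, T and NK cell, B and plasma cell, complement, hypoxia, immediate VEGF response, muscle regeneration and ribosomal protein lists were not shifted on day 20 (adjusted p from 0.146 to 0.769). In all, 2123 genes rose and 1974 fell, or 30.1% of 13594 (2273 and 1669 when so centred), with 802 and 637 changed at least 2-fold (with pseudocount 500 533 and 356). Among the 31 lists 15 were higher and 7 lower. The mean of a called list lay on its side of the control mean in all 5 day 20 arrays, except in 4 of 5 for cytokines, 4 of 5 for epidermis and 4 of 5 for hair follicle. With an estimated correlation 6 calls held (adjusted p at most 0.0234): endothelial, tip cell, VEGF, pericyte, basement membrane and venous. With the unassigned array counted as a control, 1320 genes rose and 1034 fell.

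**Figure D3:**
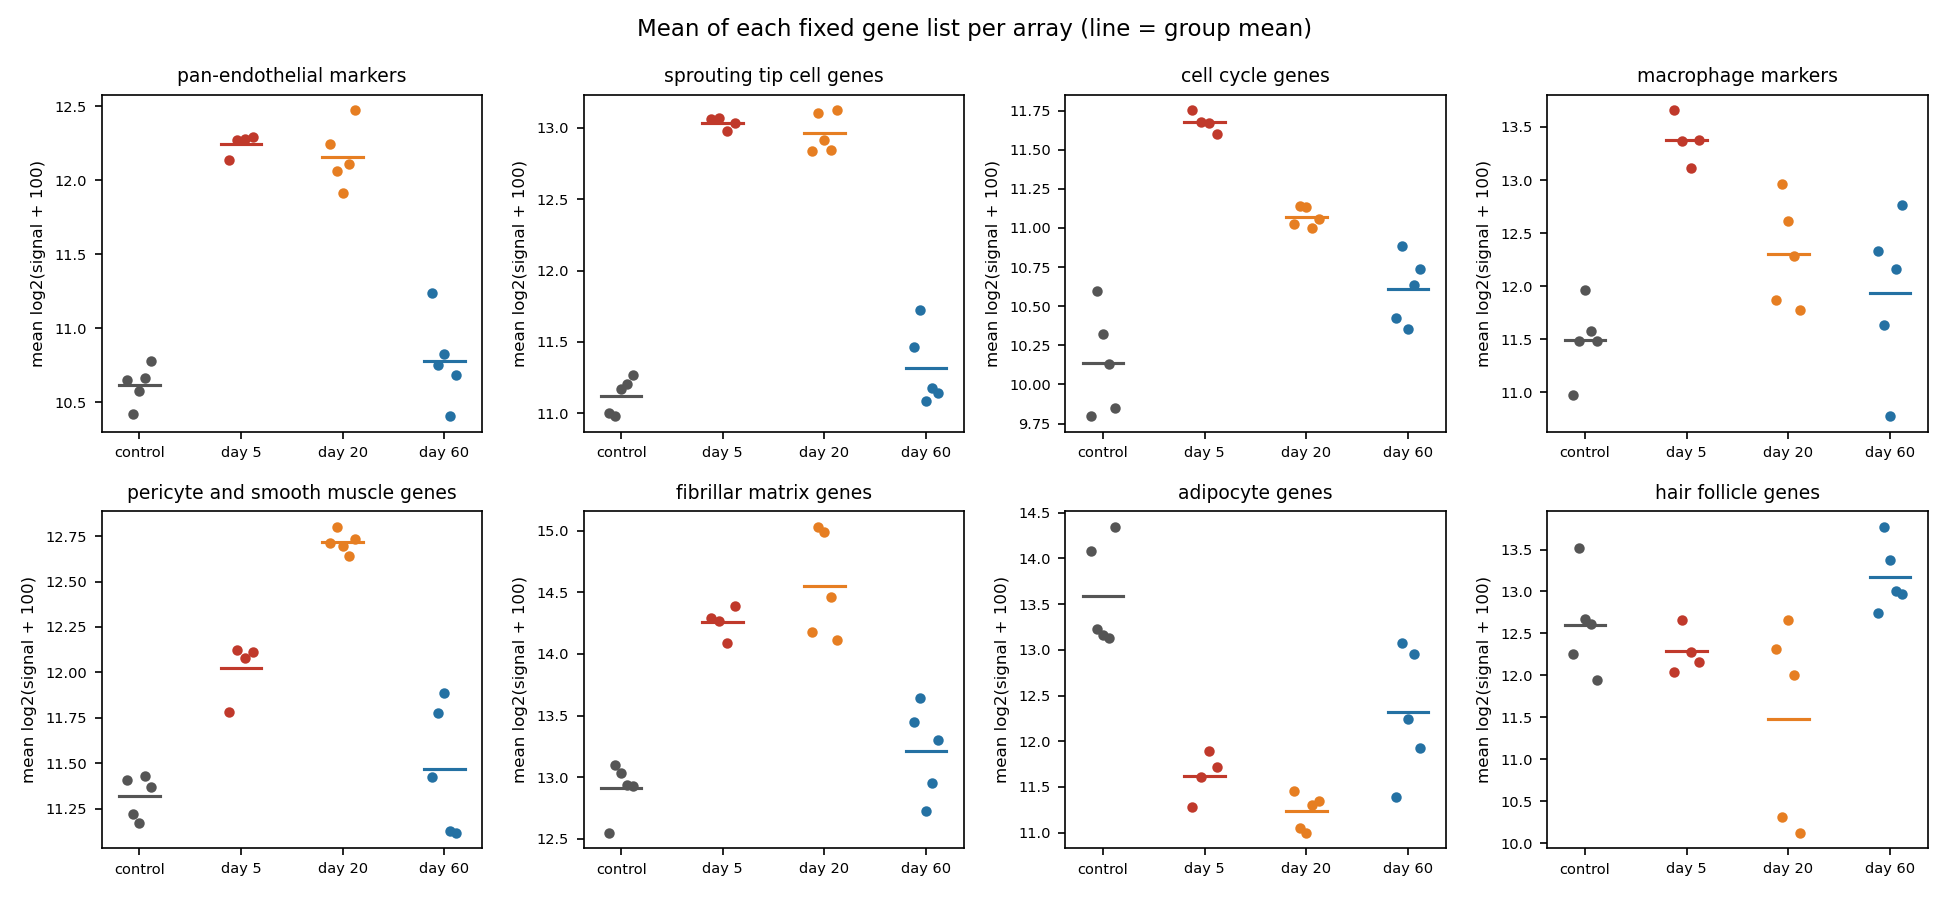
Mean log2(signal + 100) of the tested members of 8 gene lists, with 1 point per array in each of the 4 groups. The pan-endothelial list has 30 members, with mean log2 changes of 1.63 on day 5, 1.54 on day 20 and 0.16 on day 60 against control, and the adipocyte list 21 members with -1.96, -2.35 and -1.27.

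Day 60 against control asked what was left late in the course. No call was made for the VEGF receptor genes or Pgf, with log2 changes of -0.18 ± 0.23 for Kdr (SE, n = 5 each, limma adjusted p = 0.734), -0.05 ± 0.25 for Flt1 (adjusted p = 0.94) and 0.57 ± 0.37 for Pgf (adjusted p = 0.461). Genes that rose were Mmrn1, a glycoprotein of lymphatic endothelium and platelets (3.76-fold, from 1021 ± 237 to 5034 ± 3577, adjusted p = 0.0293), the myeloid gene Slfn4 (2.83-fold), the DNA repair gene Rad54l (2.47-fold), Tyr, the melanin-forming tyrosinase (2.44-fold), and Fam107a (2.40-fold). The largest falls were in Clca3a2 (9.15-fold), Pck1 (7.98-fold), the epithelial protease gene Tmprss2 (5.48-fold), the lactoferrin gene Ltf (5.41-fold) and Dbp, a transcription factor with a daily rhythm (4.89-fold). Ltf went from 3978 ± 1369.6 to 640.2 ± 222 (adjusted p = 0.00238) and Dbp from 9517 ± 2376 to 1895 ± 624 (adjusted p = 0.000588). The rises were chosen by the same rule.

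The adipocyte list was lower on day 60, as 5 fell and 16 did not pass (0 and 19 over the list alone) of 21. They averaged -1.27 (adjusted p = 8.35e-17, and adjusted p = 0.185 with an estimated correlation), and the hormone-sensitive lipase gene Lipe fell 2.75-fold. Lists of thermogenic fat (-1.22, adjusted p = 0.00126, and adjusted p = 0.318 with an estimated correlation), skeletal muscle (-0.85, adjusted p = 2.87e-06, and adjusted p = 0.525 with an estimated correlation) and mitochondrial respiration (-0.46, adjusted p = 1.16e-06, and adjusted p = 0.525 with an estimated correlation) were lower, though none of their 7, 28 and 22 members passed singly. The thermogenic mean was -0.79 without control A, and without day 60 B the muscle mean was -0.26 and the mitochondrial -0.30. Of 43 cell cycle genes 6 rose and 37 did not pass (21 and 0 over the list alone). They averaged 0.47 (adjusted p = 1.62e-13, and adjusted p = 0.264 with an estimated correlation), with the topoisomerase gene Top2a (2.00-fold) and the spindle gene Prc1 (1.89-fold). Of 10 lymphatic genes 2 rose and 8 did not pass (3 and 0 over the list alone). They averaged 0.77 (adjusted p = 9.71e-05, and adjusted p = 0.185 with an estimated correlation), and besides Mmrn1 the lymphatic valve gene Foxc2 passed (2.28-fold). Of 19 Notch and arterial genes 1 rose and 18 did not pass (8 and 1 over the list alone), with a mean of 0.31 (adjusted p = 0.000797, and adjusted p = 0.318 with an estimated correlation), the passing member being Hey2 (1.82-fold). Of 9 venous genes 1 rose and 8 did not pass (3 and 0 over the list alone), with a mean of 0.45 (adjusted p = 0.00192, and adjusted p = 0.185 with an estimated correlation), the passing member being Nrp2.

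Of 20 hair follicle genes 1 rose and 19 did not pass (4 and 0 over the list alone) on day 60. They averaged 0.58 (adjusted p = 0.000603, and adjusted p = 0.525 with an estimated correlation). Tyr, which belongs to pigment cells of the follicle, was that member. Epidermis genes had a mean of 0.51 (adjusted p = 0.0228, and adjusted p = 0.594 with an estimated correlation), with none of 21 passing. Ribosomal protein genes had a mean of 0.19 (adjusted p = 0.00126) and complement genes 0.35 (adjusted p = 0.0339). The mean of 27 fibrillar matrix genes was 0.31 (adjusted p = 0.00161). No member of these lists passed, and each had adjusted p = 0.525 with an estimated correlation. Of 18 macrophage markers 1 rose and 17 did not pass (3 and 1 over the list alone). They averaged 0.44 (adjusted p = 0.00204, and adjusted p = 0.525 with an estimated correlation). Leaving out single arrays ended the complement call without control A, control B, day 60 A, day 60 D or day 60 E (adjusted p = 0.123, 0.133, 0.114, 0.0534 and 0.472), the epidermis call without control A, control E, day 60 C or day 60 D (adjusted p = 0.0978, 0.151, 0.131 and 0.0514), the ribosomal call without control C (adjusted p = 0.058) and the macrophage call without day 60 E (adjusted p = 0.068). The complement and macrophage means were 0.13 and 0.23 without day 60 E, and 0.56 and 0.73 without day 60 C. The matrix and ribosomal means were 0.20 and 0.13 without day 60 B, the ribosomal mean 0.13 without control C and the epidermis mean 0.33 without control E. The endothelial list had a mean of 0.16 (adjusted p = 0.056), with none of 30 members passing, and the VEGF (1 higher and 0 lower of 14, adjusted p = 0.154), tip cell (1 higher and 0 lower of 22, adjusted p = 0.0596), pericyte (0 higher and 0 lower of 20, adjusted p = 0.244), basement membrane (0 higher and 0 lower of 14, adjusted p = 0.866) and protease lists (0 higher and 0 lower of 21, adjusted p = 0.0596) were not shifted.

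The remaining lists were not shifted on day 60 (adjusted p from 0.0815 to 0.797). Of the 31 lists 10 were higher and 4 lower, and none of these calls held with an estimated correlation. The mean of a called list lay on its side of the control mean in all 5 day 60 arrays for the Notch, venous, lymphatic, cell cycle, adipocyte, thermogenic and hair follicle lists. It did so in 3 of 5 for complement genes and in 4 of 5 for the other called lists.

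In all, 50 genes rose and 104 fell on day 60, or 1.13% of 13594, with 12 and 63 changed at least 2-fold (with pseudocount 500 4 and 41, and 1 to 56 and 12 to 115 without single arrays) and 2155 genes at an unadjusted p under 0.05. Higher calls made up 32.5% of those changed, and 21.9% (30 against 107) when so centred. These counts rested on single arrays. Without control A, B, C, D or E in turn, the genes that rose and fell numbered 4 and 19, 326 and 267, 21 and 61, 16 and 67, and 5 and 17. Without day 60 A, B, C, D or E they numbered 6 and 28, 23 and 135, 188 and 177, 83 and 148, and 15 and 45. Leaving out arrays of the other days, which enter only through the shared spread, left 24, 26 and 23 rising genes without day 5 C, D and E (69 fell without day 5 E) and 28, 29, 22 and 28 without day 20 A, B, D and E. With only both compared groups in the limma fit, 0 genes rose and 2 fell. Of the named genes Ltf and Dbp kept their calls in that fit, and they lost them with the unassigned array as a control, against its own Vegfa signal (adjusted p = 0.174 and 0.155). No call of Clca3a2, Tmprss2, Prc1, Muc16 or Pparg ended when 1 array was left out.

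Other named genes lost their day 60 calls without single arrays. For Mmrn1 these were control A, control D, control E, day 60 A, day 60 B or day 60 E (adjusted p = 0.064, 0.0556, 0.0909, 0.0777, 0.0518 and 0.0545), and for Slfn4 control A, control E, day 60 A or day 60 E (adjusted p = 0.0632, 0.0563, 0.0523 and 0.0523). For Tyr they were control A or control E (adjusted p = 0.0578 and 0.0563), for Pck1 control A, control C, control E or day 60 E (adjusted p = 0.087, 0.0501, 0.0909 and 0.068) and for Lipe control A or control E (adjusted p = 0.0535 and 0.0547). For Top2a they were control A, control E or day 60 A (adjusted p = 0.0578, 0.0563 and 0.0523), and for Angptl4 control A, control E or day 60 A (adjusted p = 0.0578, 0.0589 and 0.0596). For Rad54l they were control A, control C, control D, control E, day 60 A, day 60 B or day 60 E (adjusted p = 0.0535, 0.0689, 0.0662, 0.0563, 0.0644, 0.0574 and 0.0523), and for Fam107a control A, control C, control D, control E, day 60 A, day 60 B or day 60 E (adjusted p = 0.109, 0.0689, 0.0556, 0.103, 0.0721, 0.0655 and 0.0509). Foxc2, Hey2 and Notum lost theirs without most arrays, with the highest adjusted p = 0.133 for Foxc2 (without control E), 0.125 for Hey2 (without control E) and 0.107 for Notum (without control A).

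**Figure D4:**
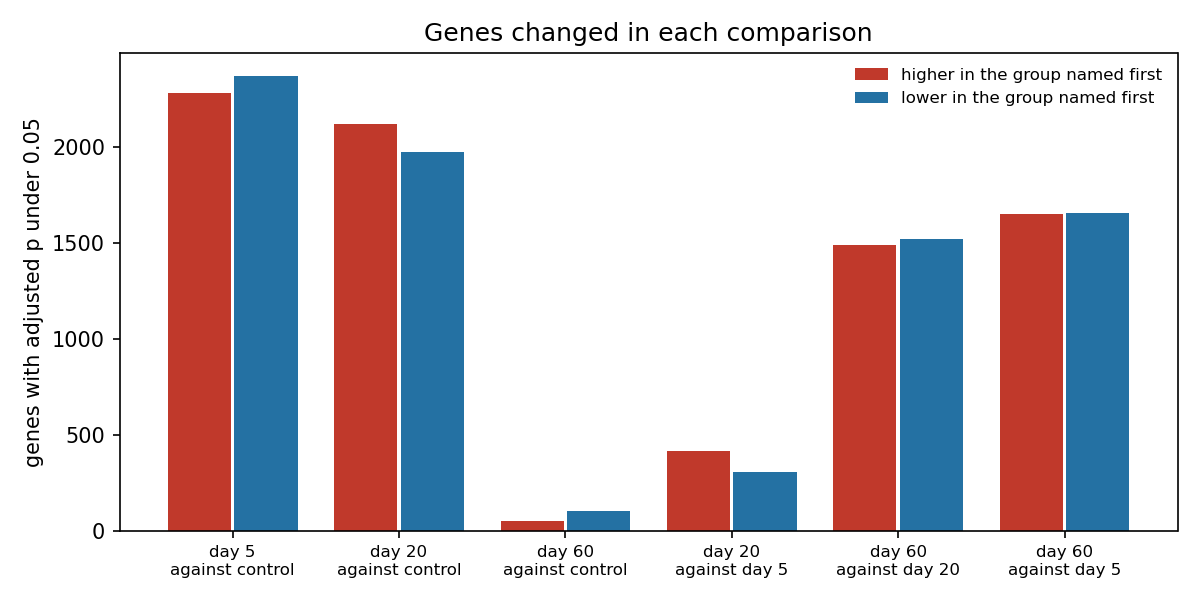
Genes called higher and lower (limma, adjusted p under 0.05, of 13594 tested) in each of the 6 comparisons, as bars from 0. Day 5 and day 20 against control have 4658 and 4097 calls and day 60 against control 154.

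Day 20 against day 5 asked how the tissue moved from early to established growth. Fmod, which encodes the collagen-binding fibromodulin, rose 10.02-fold from 719 ± 253 to 9348 ± 6374 (SD, n = 4 and n = 5; log2 change 3.33 ± 0.51, SE, limma adjusted p = 0.000852). Ecrg4 rose 8.16-fold, Mmp13 7.88-fold and Itgbl1 6.97-fold. The largest falls were in Cd163 (5.28-fold), the haem oxygenase gene Hmox1 (5.07-fold, from 5002 ± 1481 to 955 ± 408, adjusted p = 0.000121), Ms4a4c (5.06-fold) and Msr1 (4.97-fold). These genes were ranked only among passing genes whose arrays did not overlap between the days.

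Of 20 pericyte and smooth muscle genes 7 rose and 13 did not pass (10 and 0 over the list alone) from day 5 to day 20. They averaged 0.69 (adjusted p = 9.08e-08, and adjusted p = 0.146 with an estimated correlation), and the calcium pump regulator Pln rose 3.40-fold. Venous (2 rose and 7 did not pass (4 and 0 over the list alone) of 9, mean 0.48, adjusted p = 0.00893, and adjusted p = 0.279 with an estimated correlation) and fibrillar matrix genes (3 rose, 1 fell and 23 did not pass (4 and 1 over the list alone) of 27, mean 0.30, adjusted p = 0.00534, and adjusted p = 0.794 with an estimated correlation) were higher. Of 43 cell cycle genes 15 fell and 28 did not pass (0 and 29 over the list alone). They averaged -0.60 (adjusted p = 7.89e-18, and adjusted p = 0.25 with an estimated correlation). Cdc20, an activator of mitotic exit, fell 2.43-fold. Of 18 macrophage markers 5 fell and 13 did not pass (0 and 12 over the list alone). They averaged -1.08 (adjusted p = 1.38e-09, and adjusted p = 0.503 with an estimated correlation). Of 27 interferon-stimulated genes 2 fell and 25 did not pass (0 and 6 over the list alone). They averaged -0.51 (adjusted p = 1.26e-06, and adjusted p = 0.507 with an estimated correlation), and the antiviral gene Oas1a fell 2.64-fold. Of 17 ribosomal protein genes 3 fell and 14 did not pass (0 and 7 over the list alone). They averaged -0.32 (adjusted p = 1.29e-05, and adjusted p = 0.688 with an estimated correlation), and Rps19 fell 1.57-fold. Epidermis genes had a mean of -0.54 with none of 21 passing (adjusted p = 0.00549, and adjusted p = 0.794 with an estimated correlation). Of 20 hair follicle genes 1 fell and 19 did not pass (0 and 1 over the list alone). They averaged -0.80 (adjusted p = 4.53e-05, and adjusted p = 0.719 with an estimated correlation). Without day 20 B or E the hair follicle mean was -0.51 or -0.46, and the epidermis mean -0.28 without B, -0.18 without E and -0.98 without C. The fibrillar matrix mean was 0.18 without B and 0.19 without C.

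In all, 415 genes rose and 306 fell from day 5 to day 20, or 5.30% of 13594. Of the 31 lists 3 were higher and 6 lower, and no call held with an estimated correlation. Pan-endothelial markers (1 higher and 2 lower of 30, adjusted p = 0.24) and tip cell genes (0 higher and 1 lower of 22, adjusted p = 0.642) were not shifted. All 5 day 20 arrays lay on the list's side of the day 5 mean, except 3 of 5 for fibrillar matrix, epidermis and hair follicle genes. The rising genes numbered 274, 239 and 263 without day 5 B, C and D, and the falling genes 195, 179, 186 and 183 without day 5 B, C, D and E and 192 and 194 without day 20 A and D. The call of fibrillar matrix genes ended without day 20 B or day 20 C (adjusted p = 0.0907 and 0.0729), that of epidermis genes without day 20 B or day 20 E (adjusted p = 0.0856 and 0.141) and that of Rps19 without day 5 B or day 5 C (adjusted p = 0.058 and 0.0531). With probe sets of shared sequence passed over, Cdc20 had a log2 change of -0.46 (adjusted p = 0.133).

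Day 60 against day 20 asked what receded. The largest falls were in Mmp13 (25.9-fold), Vegfa on its higher probe set (18.3-fold), Kcne3 (14.5-fold) and Esm1 (13.3-fold, from 30270.2 ± 5408 to 2922 ± 2556; SD, n = 5 each; log2 change -3.73 ± 0.40, SE, limma adjusted p = 2.01e-06). The largest rises were in Thrsp (10.6-fold, from 862 ± 617 to 11274 ± 10646), Foxa1 (9.03-fold), Ces1d (8.76-fold) and the methyltransferase gene Inmt (8.29-fold). All 5 arrays of each day lay apart in these genes. On the other Vegfa probe set the log2 change was 0.67 (adjusted p = 0.0181).

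Vessel lists fell from day 20 to day 60, except that the lymphatic list was not shifted (2 higher and 4 lower of 10, adjusted p = 0.31). Of 30 pan-endothelial markers 25 fell and 5 did not pass (1 and 27 over the list alone). They averaged -1.38 (adjusted p = 1.49e-23), and Emcn fell 8.81-fold. Of 22 tip cell genes 18 fell and 4 did not pass (0 and 19 over the list alone). They averaged -1.65 (adjusted p = 3.47e-19). Of 14 VEGF and angiopoietin genes 9 fell and 5 did not pass (0 and 9 over the list alone). They averaged -1.24 (adjusted p = 1.7e-07). Of 20 pericyte and smooth muscle genes 15 fell and 5 did not pass (0 and 16 over the list alone). They averaged -1.25 (adjusted p = 4.72e-12), and the pericyte receptor gene Pdgfrb fell 5.15-fold. Of 14 basement membrane genes 9 fell and 5 did not pass (0 and 11 over the list alone). They averaged -1.37 (adjusted p = 2.82e-11), and Nid2 fell 10.3-fold. Of 27 fibrillar matrix genes 1 rose, 20 fell and 6 did not pass (1 and 22 over the list alone). They averaged -1.34 (adjusted p = 6.21e-15, and adjusted p = 0.143 with an estimated correlation), and Timp1 fell 7.30-fold. Protease (2 rose, 10 fell and 9 did not pass (3 and 12 over the list alone) of 21, adjusted p = 0.00028, and adjusted p = 0.238 with an estimated correlation), Notch and arterial (1 rose, 9 fell and 9 did not pass (1 and 9 over the list alone) of 19, adjusted p = 0.000348, and adjusted p = 0.192 with an estimated correlation) and venous genes (3 fell and 6 did not pass (1 and 5 over the list alone) of 9, adjusted p = 0.0134, and adjusted p = 0.178 with an estimated correlation) were lower, with means of -0.88, -0.60 and -0.63.

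Of 43 cell cycle genes 13 fell and 30 did not pass (0 and 19 over the list alone) from day 20 to day 60. They averaged -0.47 (adjusted p = 2.09e-06, and adjusted p = 0.317 with an estimated correlation). Of the immune lists these were lower: of 16 antigen presentation genes 6 fell and 10 did not pass (0 and 7 over the list alone) (mean -0.57, adjusted p = 0.000211, and adjusted p = 0.238 with an estimated correlation) and of 27 interferon-stimulated genes 9 fell and 18 did not pass (0 and 9 over the list alone) (mean -0.46, adjusted p = 0.00167, and adjusted p = 0.452 with an estimated correlation). T and NK cell markers (2 fell and 6 did not pass (0 and 3 over the list alone) of 8, mean -0.58, adjusted p = 0.015, and adjusted p = 0.192 with an estimated correlation), cytokines (1 rose, 5 fell and 14 did not pass (1 and 7 over the list alone) of 20, mean -0.47, adjusted p = 0.0282, and adjusted p = 0.496 with an estimated correlation) and macrophage markers (1 rose, 4 fell and 13 did not pass (1 and 5 over the list alone) of 18, mean -0.37, adjusted p = 0.0274, and adjusted p = 0.63 with an estimated correlation) were also lower. The macrophage call ended without day 20 B, day 20 C, day 60 B or day 60 C (adjusted p = 0.138, 0.0838, 0.0627 and 0.363), and the cytokine call without day 20 B, day 20 C, day 60 B or day 60 C (adjusted p = 0.0717, 0.0939, 0.0652 and 0.0794). The macrophage mean was -0.08 without day 60 C, -0.20 without day 20 B and -0.58 without day 60 E, and the interferon mean -0.30 without day 60 C.

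Skin and adipocyte lists rose from day 20 to day 60, while thermogenic fat was not shifted (0 higher and 0 lower of 7, adjusted p = 0.462). Of 21 epidermis genes 15 rose and 6 did not pass (15 and 0 over the list alone). They averaged 1.75 (adjusted p = 2.18e-08, and adjusted p = 0.238 with an estimated correlation). Of 20 hair follicle genes 15 rose and 5 did not pass (18 and 0 over the list alone). They averaged 1.69 (adjusted p = 5.72e-10, and adjusted p = 0.238 with an estimated correlation). Of 21 adipocyte genes 11 rose, 1 fell and 9 did not pass (12 and 1 over the list alone), with a mean of 1.08 (adjusted p = 0.000182, and adjusted p = 0.414 with an estimated correlation), the member that fell being Pparg, the regulator of fat cell formation. Of 10 Schwann cell genes 5 rose and 5 did not pass (6 and 0 over the list alone) (mean 0.65, adjusted p = 0.00273, and adjusted p = 0.178 with an estimated correlation) and of 17 ribosomal protein genes 4 rose and 13 did not pass (4 and 0 over the list alone) (mean 0.35, adjusted p = 0.000182, and adjusted p = 0.414 with an estimated correlation). In all, 1489 genes rose and 1522 fell, or 22.1% of 13594 (1226 and 1704 when so centred), with 521 and 562 changed at least 2-fold (with pseudocount 500 304 and 360). Of the 31 lists 5 were higher and 15 lower. Endothelial, tip cell, VEGF, pericyte and basement membrane calls held with an estimated correlation (adjusted p at most 0.0115). The mean lay on the list's side of the day 20 mean in all 5 day 60 arrays for each called list except macrophage markers (3 of 5).

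Day 60 against day 5 spanned the whole course. The largest falls were in Kcne3 (26.5-fold), Tmem255a (15.9-fold), Ms4a4c (15.1-fold) and Notch4 (15.04-fold). The largest rises were in Inmt (16.2-fold, from 232 ± 50.6 to 5613 ± 2129; SD, n = 4 and n = 5; log2 change 4.02 ± 0.39, SE, limma adjusted p = 8.03e-07), the fibroblast gene Pi16 (12.7-fold), Pgr (10.6-fold) and Scara5, a ferritin receptor (9.80-fold). Arrays of the days did not overlap in these genes. Of 30 pan-endothelial markers 1 rose, 25 fell and 4 did not pass (1 and 27 over the list alone). They averaged -1.47 (adjusted p = 2.45e-22), and Icam2 fell 14.4-fold. Of 22 tip cell genes 1 rose, 17 fell and 4 did not pass (1 and 20 over the list alone). They averaged -1.72 (adjusted p = 1.44e-18). Of 43 cell cycle genes 38 fell and 5 did not pass (0 and 39 over the list alone). They averaged -1.07 (adjusted p = 9.84e-22, and adjusted p = 0.0586 with an estimated correlation), and the kinesin gene Kif20a fell 4.25-fold. Of 27 interferon-stimulated genes 14 fell and 13 did not pass (0 and 24 over the list alone). They averaged -0.97 (adjusted p = 2.59e-10, and adjusted p = 0.182 with an estimated correlation), with the chemokine gene Cxcl9 (4.61-fold). Of 18 macrophage markers 14 fell and 4 did not pass (0 and 14 over the list alone). They averaged -1.45 (adjusted p = 4.38e-09, and adjusted p = 0.257 with an estimated correlation), and Msr1 fell 7.85-fold.

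Also lower on day 60 than on day 5, by their mean log2 change, were the VEGF (-1.07, adjusted p = 7.09e-05, and adjusted p = 0.0586 with an estimated correlation), basement membrane (-1.19, adjusted p = 1.92e-07, and adjusted p = 0.0586 with an estimated correlation), fibrillar matrix (-1.05, adjusted p = 4.68e-08, and adjusted p = 0.293 with an estimated correlation), pericyte (-0.56, adjusted p = 0.000537, and adjusted p = 0.187 with an estimated correlation) and antigen presentation lists (-0.61, adjusted p = 1.38e-05, and adjusted p = 0.206 with an estimated correlation). Members that rose and fell numbered 2 and 8 of 14, 0 and 8 of 14, 3 and 18 of 27, 2 and 7 of 20, and 0 and 9 of 16. The cytokine (-0.80, adjusted p = 0.00751), protease (-0.59, adjusted p = 0.012) and Notch lists (-0.47, adjusted p = 0.026) were lower. Each had adjusted p = 0.489 with an estimated correlation. In them 3 and 6 of 20, 2 and 7 of 21, and 1 and 6 of 19 members rose and fell. Higher were the Schwann cell (0.95, adjusted p = 0.000498, and adjusted p = 0.11 with an estimated correlation), epidermis (1.21, adjusted p = 0.000689, and adjusted p = 0.546 with an estimated correlation), hair follicle (0.89, adjusted p = 0.000904, and adjusted p = 0.546 with an estimated correlation), adipocyte (0.69, adjusted p = 0.012, and adjusted p = 0.609 with an estimated correlation) and mitochondrial lists (0.32, adjusted p = 0.0463, and adjusted p = 0.724 with an estimated correlation). Members that rose and fell numbered 5 and 0 of 10, 2 and 0 of 21, 5 and 0 of 20, 6 and 1 of 21, and 3 and 0 of 22.

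In all, 1654 genes rose and 1658 fell from day 5 to day 60, or 24.4% of 13594 (1402 and 1773 when so centred), and 1101 rose without day 5 B. Of the 31 lists 5 were higher and 13 lower. Only endothelial and tip cell calls held with an estimated correlation (adjusted p at most 0.0352). The mean lay on the list's side of the day 5 mean in all 5 day 60 arrays for each called list except the adipocyte (4 of 5) and mitochondrial lists (4 of 5). Single arrays ended the adipocyte call, without day 60 B or day 60 D (adjusted p = 0.0652 and 0.0586), the Notch call, without day 5 E or day 60 D (adjusted p = 0.0504 and 0.0685), and the protease call, without day 60 C (adjusted p = 0.0603). They also ended the mitochondrial call, without control B, day 5 B, day 5 E, day 60 C or day 60 D (adjusted p = 0.0528, 0.111, 0.0746, 0.497 and 0.0688), and its mean was 0.14 without day 60 C and 0.49 without day 60 B. Over all 6 comparisons 102 of 186 list tests were called, and mean, median and test had the same sign in each called list, while 11 lists that were not called differed among them.

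Genes were sorted by their course with the direct tests between days. Transient genes, changed on day 5 and moving back by day 60, were 57.5% of day 5 calls. The 1480 that rose (64.8% of rises) were led by Kcne3, Esm1 and Vegfa's higher probe set. The other one fell (-1.34 on day 5). The 1200 that fell (50.6% of falls) were led by Foxa1, Clca3a2 and Thrsp. Persistent genes, passing in the same direction on days 5, 20 and 60 against control, numbered 32 higher and 78 lower. The higher ones were led on day 5 by Mgp (3.57 ± 0.44, log2 change and SE), Slfn4 (3.50 ± 0.31) and Fxyd5, a regulator of the sodium pump (2.69 ± 0.13). The lower ones were led by Foxa1, Clca3a2 and H2-Q10. Late genes, changed on day 60 against control and moving the same way from day 5 to day 60, numbered 8 higher and 11 lower. Tyr, Fam107a and the Wnt inhibitor gene Notum (0.94 ± 0.22) led the higher ones. Muc16 (-1.49 ± 0.25), Pparg (-1.41 ± 0.24) and Angptl4, an inhibitor of lipoprotein lipase (-1.36 ± 0.27), led the lower ones. A gene could be in more than 1 class.

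The small classes rested on single arrays, as the day 60 calls did. Persistent genes numbered 4 higher and 14 lower without control A, 193 and 205 without control B, 16 and 48 without control C, 12 higher without control D, and 4 and 13 without control E. They numbered 4 and 20 without day 60 A, 16 higher without day 60 B, 118 and 52 higher without day 60 C and D, and 11 and 31 without day 60 E. Persistent higher genes numbered 17, 17 and 15 without day 5 C, D and E, and 21, 19, 16 and 21 without day 20 A, B, D and E. Late genes numbered 0 higher and 4 lower without control A, 59 and 17 without control B, 3 and 6 without control C, 2 and 7 without control D, and 0 and 3 without control E. They numbered 1 and 4 without day 60 A, 33 and 23 without day 60 C, and 5, 18 and 3 higher without day 60 B, D and E. Without day 5 B, C, D and E the late higher genes numbered 5, 3, 3 and 3 (6 lower without C), and without day 20 A, B, C, D and E 3, 4, 5, 2 and 3.

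Calls of different days were compared in number. On days 5 and 20, 1524 genes were higher in both and 1317 lower in both, and 12 were called in opposite directions. Independent lists of these sizes would share 356.9 and 344.6, and 100 simulations of unchanged groups against the same controls gave 0 shared calls at most. With the controls split into separate parts of 2 and 3 arrays, over 10 splits, the overlaps were 964 to 1040 higher and 573 to 686 lower. Days 5 and 60 shared 38 higher and 85 lower genes (8.4 and 18.2 for independent lists, 0 to 128 and 2 to 126 with split controls), with 3 in opposite directions. Days 20 and 60 shared 38 and 82 (7.8 and 15.1, and 0 to 77 and 2 to 103), with 5 in opposite directions. Across genes, which are not independent replicates, the log2 changes of days 5 and 20 correlated at 0.84, those of days 5 and 60 at 0.563 and those of days 20 and 60 at 0.527, while simulated unchanged groups gave 0.478, 0.469 and 0.474. The covariances were 0.443, 0.153 and 0.133, against 0.027, 0.025 and 0.024 simulated, which leaves differences of 0.416, 0.128 and 0.109.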

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

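Tests chosen only after the results were seen were those of dilution, of fewer adipocytes and luminal cells for Dbp, of the spread between day 60 arrays as the sole cause and, by their covariate, of RNA degradation. The readings of the time of day, luminal and spread tests were also settled after their values were seen.

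Single arrays stood apart from the rest of their group in 23 of 436 group tests, and chance gives about 1 in 20. By the mean log2(signal + 100) of a list, day 5 B was lowest for pan-endothelial markers (12.138), pericyte genes (11.782) and mast cell markers (9.946), and day 20 C was lowest for the VEGF list (11.769) and highest for ribosomal protein genes (15.196). Day 60 C was lowest for antigen presentation genes (11.124) and control A highest for thermogenic fat genes (13.148). By the log2(signal + 100) of a gene, day 5 B was lowest for Flt1 (12.71), Ltf (7.59) and Tyr (9.16) and highest for Rad54l (10.68). Control B was lowest for Kdr (10.07) and highest for Tnc (11.69), and control E lowest for Hmox1 (8.7). Day 5 D was lowest for Mmp13 (9.07) and day 5 C for Pgr (8.88). On day 20, array E was lowest for H2-Q10 (8.38), C for Hey2 (10.58), D for Lipe (7.98) and A for Oas1a (10.68), and B highest for Top2a (12.61). On day 60, array B was highest for Kcne3 (9) and C lowest for Msr1 (8.77).

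Skin lists moved in opposite directions on different days. Epidermis and hair follicle genes were called lower on day 20 and higher on day 60 against control (with an estimated correlation adjusted p = 0.409 for both on day 20, and adjusted p = 0.594 and 0.525 on day 60). The direct test between these days gave mean log2 differences of 1.752 and 1.692 (adjusted p = 0.238 for both with an estimated correlation), with all 5 day 60 arrays above the day 20 mean for both lists. In the unassigned array 19 of the 31 lists lay above every control array. Among 4079 tested probe sets with no gene name here, 213 were higher and 464 lower on day 5.

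Some genes of mammary luminal epithelium were among the largest falls. The 11 noticed there, picked because they fell, had a median log2 change of -3.70 on day 20, and day 60 A to E varied in the luminal keratin Krt8. RNA degradation was argued against, since the Actb 3' to 5' ratio was no higher on day 20 (4.48) than in control (7.10). With it as a covariate 15 luminal genes not looked at before kept 103% of their median change, but the covariate moved few calls. Less mammary epithelium in the harvested tissue remained open, as 53.33% of those 15 genes were lower on day 20 (median -1.04) and 6 of 15 on day 5, between the bounds set for and against it, and 13.3% peaked in day 60 D, the array highest in Krt8 (11089.2), which B nearly equalled (11008.5). Uniform dilution by new cells also remained open for the luminal genes. The luminal median lay -0.157 from the skeletal muscle median (2 SE 0.65) and -0.622 from the Schwann cell median (2 SE 0.646). The medians of 5 resident lists were spread over 3.63 SE. The time after the vector and the vector itself were not tested apart from these.

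Dbp was lower than control on each day. A different time of day at harvest is a candidate explanation that cannot be told apart from the groups: genes in antiphase to Dbp exceeded genes in its phase by a median log2 difference of at least 0.917 on each day, but the antiphase median on day 5 was -0.013. Fewer adipocytes and luminal cells stayed open as well. In the only day 60 array that kept control levels of Adipoq and Krt8, array B, Dbp was 4.386 times below the lowest control, which is a single array. Over all day 60 arrays the Dbp change lay -1.162 from the median of 47 adipocyte and luminal genes with 2 SE of 0.609, yet -0.36 from the luminal genes seen with 2 SE of 0.641.

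Few genes passed on day 60 against control. Spread between the day 60 arrays as the sole cause was argued against, since the median ratio of day 60 to day 5 change reached at most 0.414 over 20 ways to split the controls. RNA degradation stayed open: the Actb covariate gave 164 calls, not 154, and omitting single arrays moved them more. Larger spread as a part of the cause cannot be told apart from the rest, because the median SD within day 60 was 1.092 times that within control, and 0.981 to 1.315 times with an array left out.

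Other splits of the same arrays were counted, 100 for each comparison with the real one included. Chance was argued against where the real split called the most genes. It did so for day 5 against control (4658 genes, at most 3831 in other splits, 1 split as large). It also did for day 20 against control (4097, at most 1010, 1 split) and day 20 against day 5 (721, at most 208, 1 split). The same holds for day 60 against day 20 (3011, at most 489, 1 split) and day 60 against day 5 (3312, at most 2196, 1 split). For day 60 against control 3 of 100 splits called as many as the real 154, a small share that does not exclude chance. The real split was not the largest, as another called 339, and this count rested on single arrays.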

How the results depend on the processing

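Joint omissions and the covariate were chosen after the results were seen. Counts for day 5 and day 20 against control, for day 60 against day 20 and for transient genes stayed within 1.5 times under each single omitted array. Over those omissions they ran from 1972 to 2389 higher and 1867 to 2557 lower for day 5, 1725 to 2234 and 1448 to 2170 for day 20, 1123 to 1616 and 1186 to 1617 for day 60 against day 20, and 1198 to 1517 and 805 to 1391 for transient genes. Of the calls of lists under an omitted array 1895 stood and 43 were lost, and with quantile normalization 101 of 102 stood. Low signal limits small changes, because 37.8% to 40.2% of probe sets per array lay under 300 on average by group. Causes are given only where the construction shows them.

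Omitting each array in turn moved the day 60 calls from 4 to 326 higher and from 17 to 267 lower, with the lowest values without control A and control E and the highest without control B for both. Persistent genes ran from 4 (without control A, control E or day 60 A) to 193 higher and from 13 (without control E) to 205 lower, both highest without control B. Late genes ran from 0 (without control A or E) to 59 higher (without control B) and from 3 (without control E) to 23 lower (without day 60 C). Day 20 against day 5 ran from 239 (without day 5 C) to 513 higher (without day 60 B) and from 179 (without day 5 C) to 363 lower (without control B), and day 60 against day 5 from 1101 (without day 5 B) to 1771 higher (without control B). Lists higher on day 20 than on day 5 numbered 3 to 5, and lists higher on day 60 than on day 5 numbered 3 to 6. The cause was not tested.

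The filter and scaling moved small counts. With no minimum signal, 28 genes were higher on day 60, 19 persistent higher, 4 late higher, and 5 lists were higher on day 20 than on day 5. With a minimum of 1000, 67 genes were lower on day 60, 51 persistent lower and 7 late lower. With the 75th percentile, 30 were higher on day 60, 21 persistent higher and 3 late higher, and without a trend in eBayes 4 were late higher. The cause was not tested. With pseudocount 1 and quantile normalization no count moved by over 1.5 times. With pseudocount 500 the only counts to do so were those of genes changed at least 2-fold, as adding more to each signal shrinks fold changes: 510 lower on day 5 (818 in the main setting), 533 higher and 356 lower on day 20 (802 and 637), 4 and 41 on day 60 (12 and 63), 304 and 360 on day 60 against day 20 (521 and 562), 92 higher on day 20 against day 5 (160) and 261 higher on day 60 against day 5 (498). Counted as a control, the unassigned array left 430 and 387 genes at least 2-fold lower on days 5 and 20.

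Array weights, which count variable arrays less, called 147 genes higher on day 60, 934 higher and 819 lower on day 20 against day 5, 96 persistent higher, and 25 late higher and 19 lower. With only both compared groups in the limma fit, which leaves fewer arrays to estimate the spread, 0 genes were higher and 2 lower on day 60, 493 lower on day 20 against day 5, 0 and 2 persistent, and 0 late higher and 0 late lower, beside the 2155 genes at an unadjusted p under 0.05 on day 60 with all arrays in the fit. With the mean of all probe sets of a gene, 7 were higher and 56 lower on day 60, 269 higher on day 20 against day 5, 7 and 43 persistent, and 0 late higher. With probe sets of shared sequence passed over, 28 were higher on day 60, 20 persistent higher and 4 late higher. That setting replaced the probe set of Vegfa by the other one and turned its log2 change to -1.34 on day 5, -0.89 on day 20 and 0.67 on day 60 against day 20. Testing all probe sets, a larger number of tests, called 3828 higher and 4001 lower on day 5, 3378 and 3218 on day 20, 494 lower on day 20 against day 5, 2443 and 2433 on day 60 against day 20 and 2700 and 2829 on day 60 against day 5.

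The labels do not say whether equal letters A to E of the titles mark paired samples, so no pairing was used in the main setting. In no comparison did every pair correlate over 0.1. Over 27 pairs of arrays with the same letter, deviations from group means correlated from -0.275 to 0.348, with a mean of 0.052. With the letter as a replicate block 32 genes were higher on day 60, and 2 were late higher and 7 late lower.

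Counted as a day 5 array, the unassigned array left 5 lists higher on day 20 than on day 5. Counted as a control, which its Vegfa signal goes against, it left 1269 genes lower on day 5, 1320 higher and 1034 lower on day 20, 0 higher and 0 lower on day 60 in limma, 225 and 125 on day 20 against day 5, 0 and 0 persistent, 613 transient lower, and 0 late higher and 0 late lower. The cause was not tested. Without day 60 A and B together, 3 genes were higher and 43 lower on day 60, 3 and 35 persistent, and 0 late higher and 6 lower. Without control B and day 60 A together, 208 were higher on day 60, 139 persistent higher and 42 late higher. With the control arrays split, the median overlap was 1004.5 higher and 636 lower for days 5 and 20, 2.5 and 8 for days 5 and 60, and 3 and 7 for days 20 and 60, with fewer controls in each test.

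With an estimated correlation, 4 lists were higher on day 5 and 6 on day 20, and 0 lower. Day 60 against control and day 20 against day 5 had 0 of both. Day 60 had 5 lower against day 20 and 2 against day 5, and 0 higher. Of 102 list calls 17 stood, and the other 85 kept their direction and missed the threshold. Directional fry called 4 lists higher and 1 lower on day 60, 1 lower on day 20 against day 5, and 1 higher on day 60 against day 5.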

Other observations

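The members named in this part were chosen after their values were seen.

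Red cell and platelet lists were too short to be tested. Of 3 erythroid genes 2 rose on day 5 and 3 on day 20 against control: the anion exchanger gene Slc4a1 (log2 changes 1.66 ± 0.50 and 2.19 ± 0.47, SE, limma adjusted p = 0.0143 and 0.00157), the haem synthesis gene Alas2 (1.08 ± 0.37 and 1.88 ± 0.35) and, on day 20, Bpgm (1.35 ± 0.30). Of 4 platelet genes Ppbp rose on both days (1.499 ± 0.55 and 3.75 ± 0.51) and fell from day 20 to day 60 (-2.30 ± 0.51, adjusted p = 0.00307), and Pf4 rose on day 5 (1.17 ± 0.23). Itga2b and Treml1 passed in no comparison. None of the 7 passed on day 60 against control, though the erythroid mean lay above every control in 4 of 5 day 60 arrays.

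Some lists that were not shifted held members that moved far. Among hypoxia and glycolysis genes Bnip3 and Pfkfb3 fell on day 5 (log2 changes -1.90 ± 0.28 and -1.82 ± 0.31, SE, adjusted p = 4.2e-05 and 0.000145) while Adm, which encodes the vessel peptide adrenomedullin, rose (1.86 ± 0.30, adjusted p = 9.12e-05). Among neutrophil markers Ltf (-3.24 ± 0.34) and Lcn2 (-3.13 ± 0.74), which epithelium also makes, fell. Within the antigen presentation list, which was higher on day 20 with a mean of 0.64, the class II genes H2-Eb1, H2-Aa and Cd74 rose most (2.27, 2.17 and 1.88).

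The labels put 1 array in no group. Its signals were 11111.1 and 788.3 on the Vegfa probe sets, 26127.8 for Esm1, 6099.5 for Kdr, 582.7 for Krt8, 3219.4 for Adipoq and 1249.8 for Dbp, with an Actb 3' to 5' ratio of 3.1. Its correlation with the group means was 0.931 for control, 0.976 for day 5, 0.966 for day 20 and 0.942 for day 60.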
